A study of Rattus norvegicus with 4 samples.

How the data were processed

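Total RNA from the livers of 4 female Fischer rats given ciprofibrate was compared with a pool from 5 control rats on 4 two-colour cDNA arrays, per the labels. The labels state that each array holds 1 of the 4 treated rats but do not number the rats, so each array was taken as a different rat; if any were shared, the p-values would measure technical spread. Replicate numbers follow the order of the samples and only name them.

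The authors deposited 1 value per spot and array, in a table that names no unit. From the values, the deposited unit is log10 of a ratio: 10 to the power of the value, in thousandths, was a whole number within 0.02 for 100.0% of the spots on each array, against about 3% when base 2 was tried (between 2.72% and 3.07%). The direction is not stated. The medians of the deposited values were -0.02, -0.04, -0.03 and -0.05 (log10) on replicates 1 to 4. The scanner, background correction, spot filter and normalization are not given in the sources used here. On each array a single value recurred on 1171, 1177, 1189 and 1184 spots, at a linear ratio of 0.744, 0.746, 0.799 and 0.786; it was read as a spot with no measured ratio and set to missing. That reading, and the reading that the authors scaled each array by one factor, were inferred from the values. The table holds no intensities, so neither loess normalization nor a check against background could be made, and weak spots cannot be told from strong ones except where a ratio is missing.

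The values were converted to log2. Gene names come from an older platform annotation through the probe numbers. It lists 5252 of the 7688 probes; 5169 had 1 gene symbol, 83 had several and 2436 were not listed, which leaves them unnamed here. Symbols were updated through the Entrez number in a table of the GRCr8 assembly for 5140 probes, and 29 kept the listed symbol. No gene was named, or entered a list or the panel, from a clone with several symbols. A clone of Cyp4a1 with its symbol listed more than once was treated likewise. Clone sequences were not checked. Spots of one listed clone were averaged (5674 rows, unlisted spots included) and each array was centred on its median. The shift of each array by centring lay between -0.08 and 0.03 (log2). Each of the 2436 unlisted spots stayed a row of its own and is called a clone in the counts. A sequence printed more than once among them was therefore not averaged and could be counted more than once. Clones with a value on all 4 arrays were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes), as the mean log2 ratio against 0, with Benjamini-Hochberg adjustment and a threshold of 0.05, two-sided. An exact sign-flip test of 4 arrays cannot give a p below 0.125, so no single clone could pass one; the limma test borrows its estimate of spread from all clones. The pool counts as 1 control sample and the test leaves out the spread between control rats.

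Whether the row unit is the clone or the spot was settled after both counts had been seen, since the plan named the feature as deposited; with every spot as its own row, 866 were positive and 982 negative. Gene groups were tested on genes, with clones of a gene averaged per array, by limma's camera with a preset correlation of 0.01 over the 24 of 28 lists with at least 5 measured genes. Camera compares a list with the other genes; camera with an estimated correlation and fry, which asks whether a list moves one way on balance, were alternatives. The lists, the orientation panel, the tests, the rule for named genes and most alternatives were fixed before the data were examined. The rule took the 12 clones with the largest positive and the 12 with the largest negative mean past the threshold, with 1 symbol and one sign on every array; then up to 4 members of each list with at least 3 measured genes, the 2 with the smallest p of each sign among those called, or the 2 with the smallest p where none was; and every measured member of the panel. Values in the paragraphs on gene groups are from the gene-level fit and those of the largest ratios from the clone-level fit.

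The slide layout is an inference. Neighbouring spots repeated with a period of 31, with an autocorrelation of 0.450 at that lag against 0.423 and 0.406 at the lags just below and above on replicate 3, and the values were laid out as 8 blocks of 31 by 31 spots, in 2 columns and 4 rows. After the slide maps had been seen, a robust loess surface over the positions (span 0.05, degree 1, 4 iterations, the only span tried) was subtracted from each array as an added alternative, and the median of each block as another. Neither replaces the planned values. Alternatives planned before were no centring, quantile normalization, one spread for all arrays, values on at least 3 or 2 arrays, a robust prior, array weights, each array left out, an unmoderated statistic, a minimum of 2-fold, limma's treat against 1.2-fold, one row per gene, other list tests and Spearman correlation.

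The tests were tried on simulated data with the 4704 clones' own spreads and 200 changed clones per set, in 10 sets each. A change of 0.5 (log2) was recovered in 49.6% and a change of 1 in 88.6% of the changed clones, with 5.6 and 9.6 unchanged clones called per set on average. With no change, 0 clones were called. With the fitted position surfaces added and no change, 0 were called too, but with 200 clones changed by 1 on top of the surfaces, 56.6 unchanged clones were called per set. In 20 simulated sets a list of 14 genes shifted by 0.5 was called 20 times and unshifted lists 0 times. A known surface was recovered with a correlation of 0.996.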

Results

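Liver RNA was profiled on 4 two-colour cDNA arrays, a format in which 2 RNA samples labelled with different dyes compete for the same spotted cDNA clones. Each array set total RNA from the liver of 1 female Fischer rat given ciprofibrate daily over 60 days, at 50 mg per kg of body weight, against one pool of total RNA from 5 control rats. Ciprofibrate is a fibrate, a lipid-lowering drug that activates the nuclear receptor PPARα and acts as a peroxisome proliferator in rodent liver. The series title gives the question as the gene expression that ciprofibrate stimulates in rats. The table held 7688 spots per array, of which 6517, 6511, 6499 and 6504 carried a measured ratio on replicates 1 to 4. Spots of one listed clone were averaged, and each unlisted spot stayed a row of its own. Keeping rows with a value on all 4 arrays left 4704 for testing, called clones here, 2707 of them with 1 gene symbol. Averaging the clones of one gene gave 2644 genes for the gene groups. The number of arrays limits the precision, since each mean rests on 4 rats.

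The labels name the treated liver as channel 1 and the control liver as channel 2 and give no dyes, so the direction of the ratio was not settled by them. A panel of 24 textbook genes induced by peroxisome proliferators, written before the data were examined, was used to bear on it. Under 1 gene symbol, 9 were measured on all 4 arrays. Of these, 6 had a positive and 3 a negative mean log2 ratio. A positive log2 ratio is therefore read as likely higher in the treated rats, on the basis of the channel order and of this majority, which is a narrow one. Without replicate 2 it was 5 to 4, with Cpt2 at -0.0049 and Hsd17b4 at -0.10, and without each of the other arrays 6 to 3, with Hsd17b4 at -0.60 without replicate 1. Past the threshold lay Ech1, a dienoyl-CoA isomerase of fatty acid oxidation, at 0.67 ± 0.10 (log2, SD, n = 4), Me1, the cytosolic malic enzyme that supplies NADPH, at 0.43 ± 0.08, and Acsl1, a long-chain acyl-CoA synthetase, at 0.41 ± 0.22. Acot2, a mitochondrial acyl-CoA thioesterase, passed it in the other direction at -0.39 ± 0.09. The remaining members did not pass: Decr1 was at 0.41 ± 0.40, Acadm at 0.28 ± 0.15, Cpt2 at 0.05 ± 0.14, Cpt1a at -0.22 ± 0.19 and Hsd17b4 at -0.36 ± 0.63. Clones listed under several symbols, or with a symbol repeated as for Cyp4a1, were not counted in the panel, although some carry names of its genes. The clone listed for Cyp4a2 and Cyp4a3 was at 0.89, that for Acot1 and Acot3 at 0.89 and that for Cyp4a1 at 0.31. These clones were positive on every array. The direction of the 9 counted panel genes is not independent evidence of a treatment effect, because they were used to read the sign. With a smooth surface over the spot positions subtracted from each array, 6 members were again positive, the calls of Acsl1 and Acot2 ended, and Cpt1a became a negative call at -0.35 ± 0.09 (SD, n = 4, limma adjusted p = 0.0252).

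The comparison of the treated livers with the control pool gave its largest named ratios on the negative side. The clone of Arf2, a small GTPase of vesicle transport, had a mean log2 ratio of -2.22 ± 0.83 (SD, n = 4), a 4.65-fold difference. It was followed by the clones of Pum2, an RNA-binding repressor of translation, at -1.89 ± 0.32, Ecpas, a proteasome adaptor, at -1.77 ± 0.33, Mplkip at -1.76 ± 0.41 and Add1, a protein of the membrane skeleton, at -1.69 ± 0.29. Dusp1, a phosphatase that inactivates MAP kinases, was at -1.64 ± 0.56, Bst2, an interferon-induced membrane protein, at -1.63 ± 0.14 and Akt2, a kinase of insulin signalling, at -1.56 ± 0.25. Scaf8 was at -1.55 ± 0.72 and Id4, an inhibitor of helix-loop-helix transcription factors, at -1.52 ± 0.63. Each of these 10 clones was negative on all 4 arrays, passed the threshold (limma adjusted p from 0.000183 to 0.00698) and stayed a negative call without the position surface and without any 1 array. Aifm3, at -1.57 ± 1.2, and Srxn1, at -1.55 ± 0.92, lost their clone-level call without the surface, and Aifm3 also without replicate 1 (-1.22, adjusted p = 0.0907) or replicate 3 (-1.24, adjusted p = 0.0631). Most of both ratios was left without the surface, -1.23 ± 1.2 for Aifm3 and -1.35 ± 0.98 for Srxn1 (limma adjusted p = 0.0869 and 0.0524). The gene-level call of Srxn1 held there (adjusted p = 0.0442).

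The largest positive ratios among clones with 1 gene symbol were smaller. The clone of Crmp1, best known as a neuronal phosphoprotein of axon guidance, was at 1.13 ± 0.44 (SD, n = 4, limma adjusted p = 0.00557), a 2.18-fold difference, and was the only clone with 1 gene symbol to pass the threshold at 2-fold or more in this direction. Tpm1, an actin-binding tropomyosin, was at 0.79 ± 0.21, Hspe1, the mitochondrial chaperonin Hsp10, at 0.78 ± 0.12, Ldha, a lactate dehydrogenase subunit, at 0.73 ± 0.09 and Acaa2, the mitochondrial 3-ketoacyl-CoA thiolase, at 0.71 ± 0.08. Cma1, a mast cell chymase, was at 0.69 ± 0.11 and Zscan25, a zinc finger protein, at 0.74 ± 0.41. These 7 clones stayed positive calls without the position surface, at lower means for all but Crmp1 (Acaa2 at 0.43 ± 0.08, Hspe1 at 0.40 ± 0.10, Ldha at 0.38 ± 0.15), while Zscan25 lost its call without replicate 3 (0.57, adjusted p = 0.0586) or replicate 4 (0.69, adjusted p = 0.0539). Sod3 (0.71 ± 0.12), Aldoa (0.70 ± 0.12), Cyth2 (0.69 ± 0.17), Hnrnpl (0.68 ± 0.19) and Ptprj (0.68 ± 0.15) lost their clone-level calls without it.

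Over all 4704 clones, 638 had a positive and 706 a negative mean log2 ratio at an adjusted p under 0.05 (limma, Benjamini-Hochberg), and 12 and 124 of these reached 2-fold. Unlisted spots, each a row of its own, made up 11 of the 12 and 69 of the 124. With the position surface removed the counts were 134 positive and 534 negative, so that the positive share of the calls went from 47.5% to 20.1%, and 58 positive and 401 negative clones were called both ways. With replicate 2 also left out they were 437 and 620, a positive share of 41.3%, and 183 of the 638 positive clones were among the calls. The counts also varied with the array left out. They were 310 and 382 without replicate 1, and 880 and 904 without replicate 2. Without replicate 3 they were 100 and 322, and without replicate 4 they were 153 and 359. A fit of fewer arrays has less power, so a lower count does not show that the array left out carried the ratios. The ratio was tested against 0, so the spread between control rats does not enter and any peculiarity of the single pool is carried by all 4 arrays alike.

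**Figure D1:**
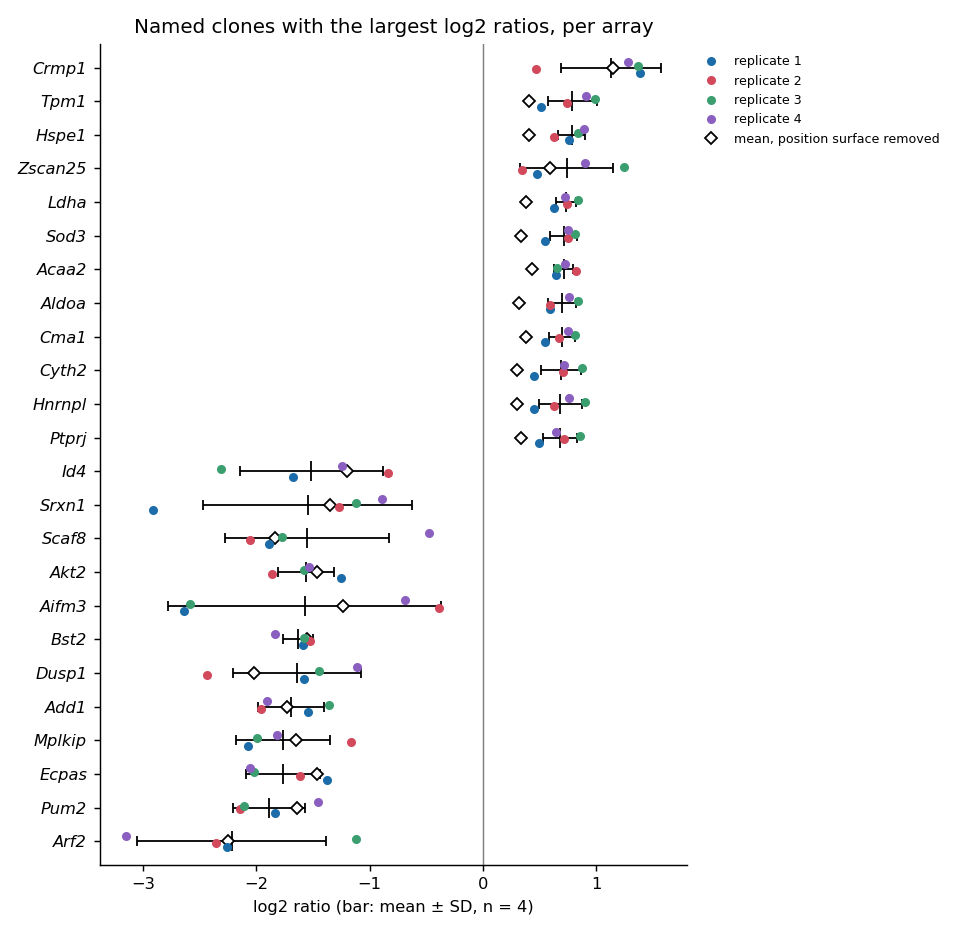
Log2 ratio of the 24 clones with the largest mean ratios (12 per sign) among those past the threshold with 1 gene symbol and one sign on every array, with one dot per array, a black bar for the mean and its SD (n = 4) and an open diamond for the mean after removal of the position surface. The negative clones lie between -1.52 and -2.22 and keep most of that size, while the positive ones other than Crmp1 lie between 0.68 and 0.79 and move closer to 0.

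The place of a clone on the slide went with its ratio. In the layout read from the values, 95.0% of the positive calls and 27.6% of the negative calls lay in the left column of printing blocks, which held 50.7% of the tested clones. The median ratio of the left blocks exceeded that of the right ones by 0.20, 0.12, 0.36 and 0.53 (log2) on replicates 1 to 4. For each gene group the number of calls that held without this surface is therefore given beside the count. Calls that arose only without it are not in these numbers: at gene level 110 were positive and 355 negative without the surface, of which 55 and 261 were also called with it. With the surface kept, 452 of all 2644 genes were positive and 440 negative calls, the base rate against which the counts of each gene group stand. Among the named genes, 44 were positive and 33 negative calls, of which 37 and 16 ended without the surface. The median ratio of the 37 went from 0.50 to 0.20 (log2) and that of the 16 from -0.48 to -0.33 at a median SD of 0.32 and 0.31, so several of the negative ones lost their call with much of their ratio left. Without replicate 1, 2, 3 or 4, respectively, 9, 1, 20 and 16 of the positive and 10, 1, 15 and 14 of the negative ones ended.

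**Figure D2:**
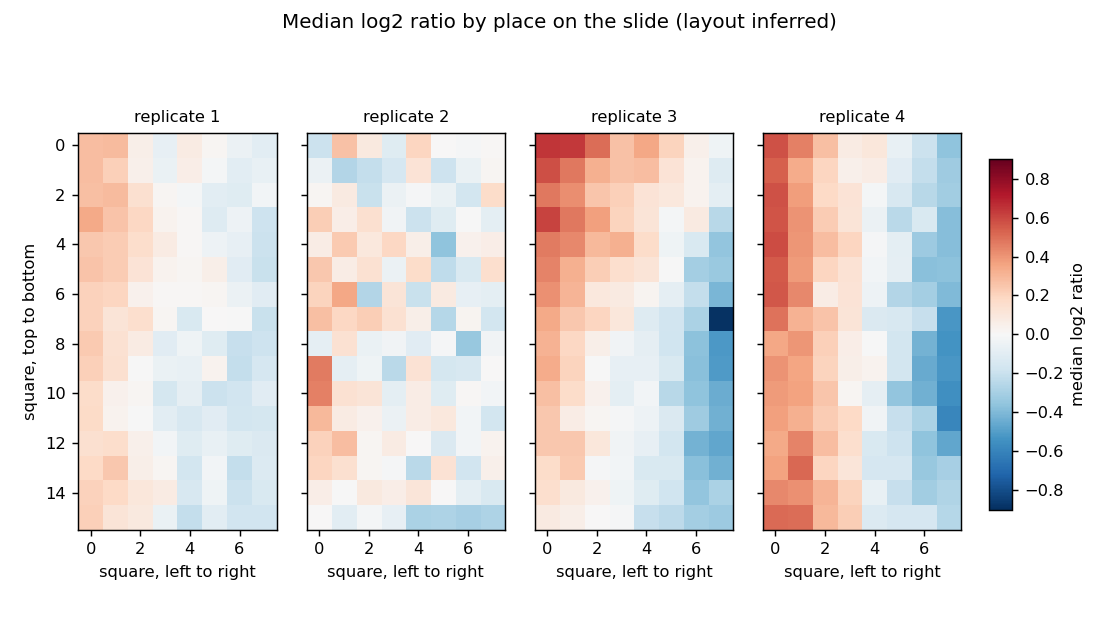
Median log2 ratio over squares of 8 by 8 spots on each of the 4 arrays, in the layout inferred from the values, with red for positive and blue for negative medians. Replicates 1, 3 and 4 run from positive at the left to negative at the right, and the squares range from -0.89 to 0.64.

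Genes of fatty acid oxidation went both ways. Of 14 measured genes of peroxisomal beta-oxidation and peroxisome biogenesis, 3 passed the threshold as positive, 2 as negative and 9 did not pass, with the same counts adjusted over the list alone. Ech1 is given above, and Crot, the peroxisomal carnitine octanoyltransferase, was at 0.67 ± 0.12 (SD, n = 4). Phyh, the hydroxylase that starts alpha-oxidation of phytanic acid, was at -1.12 ± 0.47, and Abcd3, a transporter of the peroxisomal membrane, at -0.53 ± 0.20. Without the position surface 1 of the 3 positive calls, Ech1, and both negative ones held, and Crot was at 0.28 ± 0.21. Of 16 genes of mitochondrial beta-oxidation and ketogenesis, 4 were positive, 2 negative and 10 not called, or 6 and 2 adjusted over the list alone. Acaa2 led the positive ones (0.71 ± 0.08), and Acads, the short-chain acyl-CoA dehydrogenase, was at 0.45 ± 0.18. Echs1, the mitochondrial enoyl-CoA hydratase, was at -0.61 ± 0.39. Without the surface 2 of the 4 positive calls held and neither negative one did, although Echs1 was still at -0.52 ± 0.40 (adjusted p = 0.0570). As groups neither list shifted against the other genes (camera adjusted p = 0.794 and 0.666).

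Of 7 genes of microsomal fatty acid omega-oxidation, 1 was positive, 1 negative and 5 were not called, with the same counts adjusted over the list alone (camera adjusted p = 0.821). The pair were cytochrome P450 enzymes of one subfamily, Cyp4f1 at 0.34 ± 0.15 (SD, n = 4) and Cyp4f4 at -0.70 ± 0.25, of which the second alone held without the position surface. The 7 include no Cyp4a gene, because the tested Cyp4a clones were listed under several symbols or with a symbol repeated and were left out. Those clones were at 0.89 ± 0.33 and 0.31 ± 0.14, so the list result does not cover the Cyp4a subfamily. Of 14 genes of fatty acid uptake, binding and activation, 3 were positive and none negative, also when adjusted over the list alone (camera adjusted p = 0.666). They were the binding proteins Fabp3 (0.59 ± 0.10) and Fabp4 (0.59 ± 0.11) and Acsl1, and only Fabp3 was still called without the surface, at 0.36 ± 0.15. Of 9 genes of fatty acid and triglyceride synthesis, 2 were positive and 1 negative, or 1 and 0 adjusted over the list alone (camera adjusted p = 0.602). Me1 held without the surface at 0.39 ± 0.11, and its call ended without replicate 3 (0.42, adjusted p = 0.0707). Acly, the ATP citrate lyase, at 0.31 ± 0.17, and Gpam, which starts glycerolipid synthesis, at -0.41 ± 0.31, did not hold, and without replicate 2 Gpam was at -0.26 (adjusted p = 0.0445). The call of Acly ended without each of the 4 arrays in turn (adjusted p = 0.0748, 0.0642, 0.211 and 0.102 without replicates 1 to 4). The call of Gpam ended without replicate 1 (-0.45), 3 (-0.43) or 4 (-0.50).

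**Figure D3:**
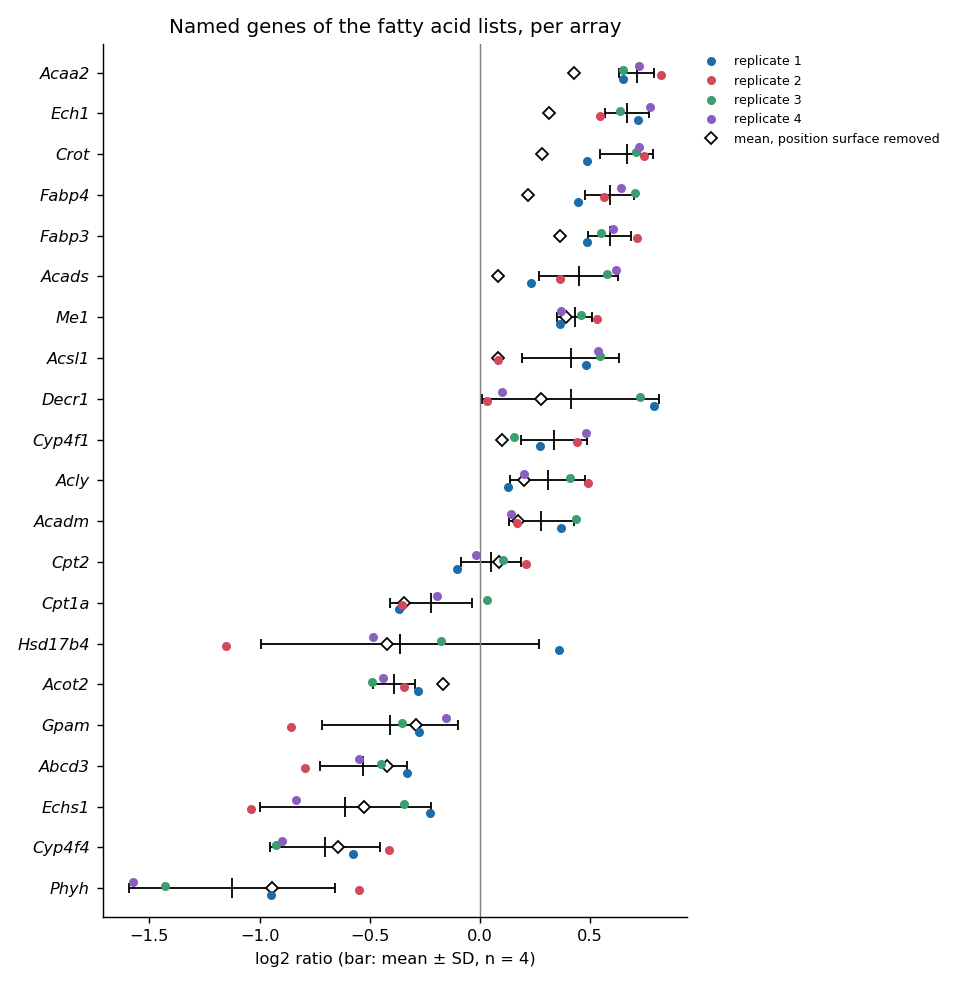
Log2 ratio of the named genes of the 5 fatty acid lists, with one dot per array, a black bar for the mean and its SD (n = 4) and an open diamond for the mean after removal of the position surface. Acaa2 and Ech1 go from 0.71 and 0.67 to 0.43 and 0.31, Phyh from -1.12 to -0.94, and replicates of Hsd17b4 lie on both sides of 0.

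The list of glucose and glycogen metabolism shifted to positive ratios (median log2 ratio 0.28, camera adjusted p = 0.0293), with 6 of 15 genes positive, none negative and 8 positive when adjusted over the list alone. The strongest were Ldha (0.73 ± 0.09, SD, n = 4) and Aldoa, a glycolytic aldolase (0.70 ± 0.12). The shift was lost with an estimated correlation (adjusted p = 0.869), without the position surface (median 0.12, adjusted p = 0.163) and without replicate 2 (median 0.25, adjusted p = 0.131). It was also lost with one spread for all arrays (adjusted p = 0.0579), with array weights (adjusted p = 0.0697) and without both the surface and replicate 2 (adjusted p = 0.436), although 3 of the 6 genes were still called without the surface. Ribosomal protein genes shifted in the same direction (median 0.23, camera adjusted p = 0.00377), with 14 of 32 positive and none negative, also adjusted over the list alone. Rpl4 was at 0.55 ± 0.18 and Rps23 at 0.52 ± 0.09. This shift too was lost with an estimated correlation (adjusted p = 0.869) and without the surface (median 0.07, adjusted p = 0.163, or 0.278 with replicate 2 also left out), where none of the 14 calls held, and it held without each single array. Both lists passed the self-contained test fry in the planned setting (adjusted p = 0.0338 and 0.0185) and not without the surface (adjusted p = 0.175 and 0.164). These were the 2 lists of 24 tested that passed camera. With the estimated correlation, 0 of the 24 had even an unadjusted camera p under 0.05. The unadjusted camera p of the respiratory chain list rose there from 0.110 to 0.162. Its estimated correlation of -0.013 lay below the preset 0.01. The loss under that alternative alone therefore says little about either list.

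Of 35 genes of the mitochondrial respiratory chain and ATP synthase, 7 were positive and 4 negative, also adjusted over the list alone. The cytochrome oxidase subunits Cox6c (0.56 ± 0.13, SD, n = 4) and Cox8a (0.49 ± 0.06) were positive, while Cyc1, cytochrome c1 (-0.56 ± 0.34), and Sdha, the catalytic subunit of succinate dehydrogenase (-0.40 ± 0.13), were negative. The list did not pass camera (adjusted p = 0.602) but passed fry as positive (adjusted p = 0.0105), and 2 of the 4 negative and none of the 7 positive calls held without the position surface. The call of Sdha ended without replicate 1 (-0.43, adjusted p = 0.0509), replicate 3 (-0.37, adjusted p = 0.100) or replicate 4 (-0.35, adjusted p = 0.0847). Of 22 chaperones, 5 were positive and 1 negative, with the same counts adjusted over the list alone (camera adjusted p = 0.602). Without the surface 1 of the 5 positive calls, Hspe1, and the negative one held. Tcp1, a subunit of the cytosolic chaperonin, was at 0.67 ± 0.15 and did not hold, and Cct6a, another subunit of it, was at -0.62 ± 0.18 and held at -0.73 ± 0.26. Of 15 proteasome genes 4 were positive and none negative, also adjusted over the list alone (camera adjusted p = 0.702), with Psmb4 at 0.50 ± 0.15 and Psmc5 at 0.35 ± 0.12, and 1 of the 4 held without the surface.

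Among genes of cholesterol synthesis and uptake, 3 of 13 were positive and 2 negative, also adjusted over the list alone (camera adjusted p = 0.812), and none held without the position surface. Msmo1 was at 0.53 ± 0.27 (SD, n = 4) and Lss, the lanosterol synthase, at 0.42 ± 0.21, against Hsd17b7 at -0.62 ± 0.55 and Nsdhl at -0.40 ± 0.20, all of them enzymes of the same pathway. Without the surface Msmo1 and Lss were at 0.27 ± 0.25 and 0.20 ± 0.19, while Hsd17b7 was still at -0.57 ± 0.58 and Nsdhl at -0.30 ± 0.15 (adjusted p = 0.0983 and 0.0508). Hsd17b7 rested on replicate 1, without which it was at -0.35 (adjusted p = 0.0747), and its call also ended without replicate 4 (-0.67, adjusted p = 0.0662). Of 4 measured genes of bile acid synthesis and transport, 1 was negative, or 2 adjusted over the list alone; it was Akr1c14, a 3-alpha-hydroxysteroid dehydrogenase, at -0.61 ± 0.35. Of 11 apolipoprotein and lipoprotein genes, 2 were negative and none positive, or 1 and 0 adjusted over the list alone (camera adjusted p = 0.602): Apoh at -0.62 ± 0.41 and Apoe at -0.54 ± 0.48. These 3 calls ended without the surface, with ratios of -0.53 ± 0.37, -0.43 ± 0.41 and -0.51 ± 0.51 left (adjusted p = 0.0507, 0.0926 and 0.0960). Apoe was at -0.33 without replicate 2 (adjusted p = 0.0475), and its call ended without replicate 3 (-0.60) or replicate 4 (-0.55).

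Secreted plasma proteins of the liver moved in both directions. Of 25 acute phase and plasma protein genes, 6 were positive and 5 negative, or 7 and 7 adjusted over the list alone (camera adjusted p = 0.799). Tf, which encodes transferrin, was at -0.69 ± 0.20 (SD, n = 4) and was 1 of 3 negative calls that held without the position surface, where none of the 6 positive ones did. Fetub was at -0.66 ± 0.42, Afp, the alpha-fetoprotein gene, at 0.53 ± 0.20 and Orm1, an acute phase glycoprotein, at 0.43 ± 0.18, and the calls of these 3 ended without it. Of 10 complement and coagulation genes, 2 were positive and 1 negative, or 3 and 2 adjusted over the list alone (camera adjusted p = 0.812). F2, which encodes prothrombin, was at -0.70 ± 0.08 and held at -0.61 ± 0.08, whereas the complement genes C1r (0.41 ± 0.10) and C4bpb (0.36 ± 0.23) did not hold. Of 25 genes of amino acid metabolism and the urea cycle, 5 were positive and 2 negative, also adjusted over the list alone (camera adjusted p = 0.666), and none held. Pccb, a subunit of propionyl-CoA carboxylase, was at 0.59 ± 0.12 and Ahcy, which hydrolyses S-adenosylhomocysteine, at 0.51 ± 0.11, against Upb1 at -0.41 ± 0.21 and Cbs, the cystathionine beta-synthase, at -0.36 ± 0.17.

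Few genes of drug metabolism passed the threshold. Of 12 cytochrome P450 genes of families 1 to 3 and their partners, 1 passed the threshold, Cyp2c23, an arachidonic acid epoxygenase, at -0.36 ± 0.24 (SD, n = 4), and none did adjusted over the list alone (camera adjusted p = 0.916). Its call ended without each of the 4 arrays in turn (adjusted p = 0.0883, 0.0509, 0.132 and 0.0644), and without replicate 2 it was at -0.25. Of 14 conjugation genes 2 were positive and none negative, also adjusted over the list alone (camera adjusted p = 0.732), the glutathione transferases Gstm7 at 0.47 ± 0.20 and Gstp1 at 0.39 ± 0.06. None of these 3 calls held without the position surface. Of 25 antioxidant and metallothionein genes, 6 were positive and 6 negative, or 7 and 7 adjusted over the list alone (camera adjusted p = 0.772). The superoxide dismutases Sod3 (0.71 ± 0.12) and Sod1 (0.50 ± 0.07) were positive and, as all 6 positive calls, did not hold, while Mt3, a metallothionein, was at -0.59 ± 0.06 and was among 5 negative calls that held. Of 9 genes of the growth hormone axis and sex-dependent expression, 2 were positive and none negative, or 3 and 1 adjusted over the list alone (camera adjusted p = 0.772): Igfals, a carrier of IGFs, at 0.32 ± 0.08 and Igfbp2, an IGF-binding protein, at 0.30 ± 0.12. Neither held, Cyp2c12 (-0.56 ± 0.21) and Stat5b (-0.37 ± 0.12), named after their values were seen, were negative calls without the surface, and Igfbp2 turned to -0.03 ± 0.15 without the surface. Of 17 cell cycle genes 3 were positive and 1 negative, also adjusted over the list alone (camera adjusted p = 0.851), with Cdc25b, a phosphatase that activates cyclin-dependent kinases, at 0.50 ± 0.10 and Rfc1, a subunit of the replication clamp loader, at 0.50 ± 0.18, and none of the 3 positive calls held. Cdkn1b, the p27 inhibitor of cyclin-dependent kinases, was at -1.25 ± 0.47 and held at -1.15 ± 0.47.

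Among markers of other cell types of the liver, the Kupffer and stellate lists were tested with camera and did not pass, and the endothelial and cholangiocyte lists were too short for it. Of 7 Kupffer cell and macrophage markers 2 were positive and 2 negative, also adjusted over the list alone (camera adjusted p = 0.916). Subunits of one complex differed in sign, C1qb at -1.23 ± 0.53 (SD, n = 4) against C1qc at 0.31 ± 0.10, and of the 4 calls C1qb alone held without the position surface, at -1.20 ± 0.58. Of 22 stellate cell and fibroblast markers 6 were positive and 4 negative, also adjusted over the list alone (camera adjusted p = 0.680), and 3 of the 4 negative and none of the 6 positive calls held. Des, the intermediate filament desmin, was at 0.62 ± 0.18 and Col5a2, a collagen chain, at 0.63 ± 0.15, and neither held, while Acta2, smooth muscle actin, at -0.61 ± 0.27, and Timp3, a metalloproteinase inhibitor, at -0.69 ± 0.29, held at -1.0 ± 0.27 and -0.50 ± 0.25. All 4 measured endothelial markers passed, Sparcl1 (0.62 ± 0.19) and Kdr (0.40 ± 0.21) as positive and Cdh5 (-0.85 ± 0.85) and Fcgr2b (-0.40 ± 0.18) as negative, also adjusted over the list alone, and none held. Cdh5 rested on replicate 3, without which it was at -0.46 (adjusted p = 0.0971), and its call also ended without replicate 1 (-1.01) or replicate 4 (-0.83). Of 3 cholangiocyte markers, Spp1, which encodes osteopontin, was positive at 0.43 ± 0.11, also adjusted over the list alone, and did not hold.

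Of 15 lymphocyte and antigen presentation markers 4 were negative and none positive, also adjusted over the list alone (camera adjusted p = 0.602). Coro1a, an actin regulator of leukocytes, was at -0.73 ± 0.17 (SD, n = 4) and Cd74, the invariant chain of MHC class II, at -0.35 ± 0.07, and these were the 2 of the 4 that held without the position surface, at -0.53 ± 0.17 and -0.62 ± 0.13. The call of Cd74 ended without replicate 1 (-0.32, adjusted p = 0.0798), replicate 3 (-0.35, adjusted p = 0.106) or replicate 4 (-0.35, adjusted p = 0.0813). Of 3 red blood cell transcripts, too few for a group test, 2 were negative, also adjusted over the list alone, Hbb, the beta-globin gene, at -0.88 ± 0.24 and Epb42, an erythrocyte membrane protein, at -0.73 ± 0.30, and both held. Alas2, an enzyme of haem synthesis named after its value was seen, was at 0.11 ± 0.22 and was not called. Of 7 adipocyte and pancreas transcripts 1 was positive and 1 negative, also adjusted over the list alone (camera adjusted p = 0.680), the carboxypeptidases Cpa1 at 0.59 ± 0.26 and Cpb1 at -0.34 ± 0.18, and neither held. Without the surface this list had 4 negative calls and no positive one, at a median of -0.32 (camera adjusted p = 0.163).

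**Figure D4:**
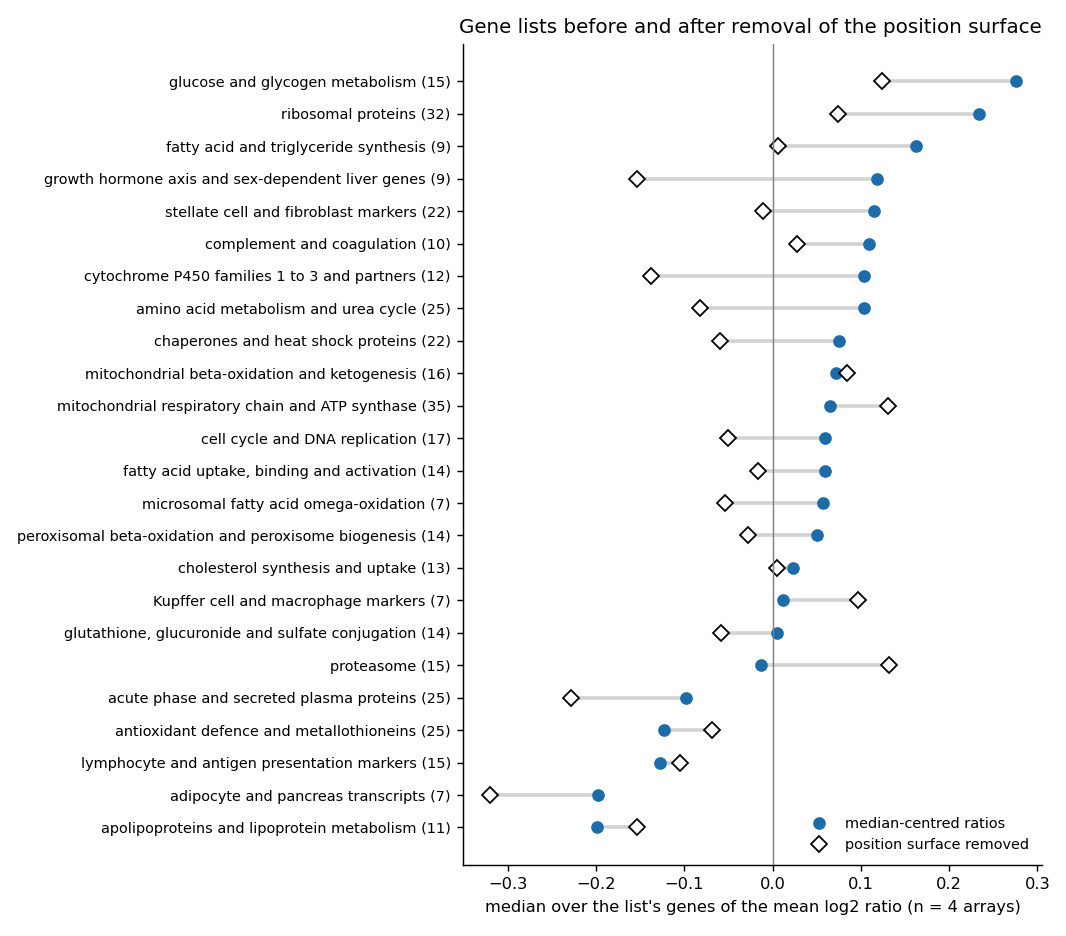
Median over each list's genes of the mean log2 ratio of 4 arrays, for the 24 lists with at least 5 measured genes (number in brackets), as filled circles for the median-centred ratios and open diamonds after removal of the position surface. The medians of glucose metabolism and ribosomal proteins move from 0.28 and 0.23 to 0.12 and 0.07.

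Across the 4704 clones the Pearson correlation between pairs of arrays lay between 0.47 and 0.76 with a median of 0.61, and 52.8% of clones had one sign on all 4 arrays. The arrays share the control pool, the channel order and a similar position surface, so a shared sign alone does not separate a treatment effect from these. Clones are not independent replicates, and no p is given for these correlations. The 3 pairs with replicate 2 had the lowest values, 0.47, 0.49 and 0.53. Without the clones past the threshold the median correlation was 0.26, and the pairs of replicate 2 with replicates 1, 3 and 4 were at -0.015, 0.11 and 0.044. The fitted position surfaces of the arrays correlated at 0.64 to 0.91, and with them removed the median correlation between arrays was 0.62. The median SD of a clone between arrays was 0.21 (log2).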

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

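In this part, the test of a bias at dim spots and the removal of the position surface were chosen after the result was seen. Each value over the 4 arrays was examined for an array whose gap to the nearest other one takes up most of the range. Of 135 values examined, 9 had such an array, where chance gives about 1 in 20, here 6.75.

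Replicate 2 stood apart in 6 of the 9. The interquartile range of its log2 ratios with the position surface removed was 0.83, against 0.28 to 0.34 on the other arrays. The median of the apolipoprotein list was -0.57 on it against -0.07 to -0.04, and that of the respiratory chain list 0.21 against 0.11 to 0.13. The clone of Crmp1 was at 0.47 against 1.28 to 1.39, Acsl1 at 0.084 against 0.48 to 0.55 and Afp at 0.83 against 0.42 to 0.45. On other arrays, Crot was at 0.48 on replicate 1 against 0.71 to 0.74, Hsd17b7 at -1.43 on replicate 1 against -0.45 to -0.25, and Epb42 at -1.17 on replicate 4 against -0.62 to -0.52.

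The width of replicate 2 and its lower correlation with the other arrays form the pattern weighed here. Random noise of single spots is argued against, because paired spots of a clone correlated at 0.904 on replicate 2, against 0.745 to 0.785 on the others, with the position surface removed. A bias at dim spots on that array may contribute: its median deviation from the mean of the others was -0.05 at clones with a missing ratio and 0.14 at clones with none, a difference of -0.19 (log2, position surface removed, two-sided permutation p = 0.00831). The larger deviation was at clones with no missing ratio. The difference is also small beside the interquartile range of 0.83 on replicate 2, so it does not by itself account for the width. The permutation p treats clones of a single array as independent and does not measure the spread between arrays or rats. Missing ratios are only a stand-in for low intensity, which was not analysed here. A difference of that rat or of its RNA stays open and was not tested.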

How the results depend on the processing

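In this part, the removal of the position surface or block medians, every spot as its own row, the restriction to clones with 1 gene symbol and the alternatives for the panel were chosen after the data were seen. No paired analysis was possible because the arrays form 1 group. Counts are positive and then negative calls, against 638 and 706, and the cause of a change was not tested unless stated. They were within 1.5 times of these with no centring (539 and 769), quantile normalization, one spread, values on at least 3 or 2 arrays, a robust prior, one row per gene and every spot as a row (866 and 982). They were 1148 and 1211 with array weights, which gave replicate 2 a weight of 0.262, and 134 and 534 with the position surface removed. With block medians removed they were 380 and 624, and with the surface removed and replicate 2 left out 437 and 620. Leaving out 1 array gave 100 to 880 positive and 322 to 904 negative calls. Stricter criteria gave fewer by construction: 12 and 124 at 2-fold, 25 and 150 with treat. The unmoderated statistic, with 3 degrees of freedom per clone, gave 6 and 4. Clones with 1 gene symbol, which are fewer, gave 457 and 444.

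Against 2 shifted lists, camera passed 0 with the estimated correlation, 0 with the surface removed and 0 with both (0, 5 and 0 at an unadjusted p under 0.05). Block medians removed gave 3, the respiratory chain list joining the 2, as did fry. One spread and array weights left 1 each, having lost the glucose list. The surface removed with replicate 2 left out gave 1, the respiratory chain list, and fry with the surface removed gave 4. Leaving out 1 array gave 1 to 2 lists. The median correlation between arrays went from 0.61 to 0.26 without the called clones, as a selection of weaker ratios does by construction. The panel had 6 positive members under 6 of its 7 alternatives and 5 without replicate 2.

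Some directions reversed, with the cause not tested; unless given otherwise, the values are list medians of results that passed no threshold. With the surface removed Igfbp2 went to -0.032, and with replicate 2 also left out to -0.11; Cpt2 went to -0.0049 without replicate 2, the lowest of a range up to 0.099 over the arrays left out. With the surface removed, under the preset and the estimated correlation and fry, reversed lists were omega-oxidation (-0.053), amino acid metabolism (-0.083), P450 families 1 to 3 (-0.14), conjugation (-0.058), the growth hormone axis (-0.15, past the threshold by fry, adjusted p = 0.00868) and stellate cells (-0.011). By fry alone there were also cholesterol (0.0048), complement (0.028), cell cycle (-0.050) and chaperones (-0.060). With replicate 2 also left out they were omega-oxidation (-0.061), cholesterol (-0.063), apolipoproteins (0.015), amino acid metabolism (-0.066), P450 (-0.11), conjugation (-0.054), the growth hormone axis (-0.11) and stellate cells (-0.0050). With block medians removed they were omega-oxidation (-0.035) and the growth hormone axis (-0.039). The Kupffer list reversed with one spread (-0.013), values on at least 3 arrays (0.012), array weights (-0.041) and without replicate 2 (-0.047, range up to 0.075). Cell cycle reversed without replicate 3 (0.064, range 0.027 to 0.078) and P450 without replicate 4 (0.0048, range up to 0.12). A median can keep its sign where the test turns. Over all alternatives of the named genes, 920 kept their direction and side of the threshold, 218 fell below it and 7 came to pass. For the named clones these were 319, 17 and 0, and for the lists 375, 13 and 6. Signal over background, which would limit weak spots, was not analysed here.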

Other observations

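In this part, the choice of clones outside the naming rule, the position surface and the tests of both patterns were made after the data were seen. Clones assigned to more than one gene were left out of the named genes, the panel and the gene lists, yet 2 of them had larger positive ratios than most named clones. A clone assigned to more than one gene of the Cyp4a subfamily, the fatty acid omega-hydroxylases induced by peroxisome proliferators, was at 0.89 ± 0.33 (log2, SD, n = 4, limma adjusted p = 0.00669) and stayed a positive call with the position surface removed, at 0.51 ± 0.29. Another clone of the subfamily was left out because its symbol, Cyp4a1, was listed more than once. It was at 0.31 ± 0.14 (adjusted p = 0.0520) and was a positive call with the surface removed, at 0.34 ± 0.15 (adjusted p = 0.0468). A clone assigned to more than one acyl-CoA thioesterase gene of type I was at 0.89 ± 0.44 (adjusted p = 0.0107) and stayed one at 0.78 ± 0.43. A clone of the sulfotransferase family 2A, whose enzymes sulfate steroids and bile acids, was at -0.77 ± 0.45 (adjusted p = 0.0166), and its call ended with the surface removed, at -0.57 ± 0.52. The other 2 clones of that family were not called, at -0.22 ± 0.27 and -0.12 ± 0.31 (adjusted p = 0.209 and 0.535). Both means rested on replicate 2, at -0.59 and -0.58, while the other arrays lay between -0.16 and 0.07.

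With the surface removed, further clones came to the front. Pomc, the precursor of ACTH, was at 0.57 ± 0.29 (log2, SD, n = 4), Fbp1, the gluconeogenic fructose bisphosphatase, at 0.44 ± 0.16 and Cfi, complement factor I, at 0.42 ± 0.12, all positive calls there (limma adjusted p = 0.0327, 0.0276 and 0.0235). Calcrl, a receptor of calcitonin-like peptides, was at -1.66 ± 0.56 and Myh10, a non-muscle myosin, at -1.57 ± 0.60 (adjusted p = 0.00777 and 0.0107). Under fry with the surface removed, 4 lists passed: the respiratory chain at a median of 0.13 and, with negative medians, the growth hormone axis (-0.15), lymphocyte and antigen presentation markers (-0.11) and adipocyte and pancreas transcripts (-0.32). Of the 24 lists, 0 passed camera there and 5 had an unadjusted p under 0.05, the lowest adjusted p being 0.163. With replicate 2 also left out 1 list passed camera, the respiratory chain. Among unlisted spots the highest mean was 1.89 ± 0.19 and the lowest -2.52 ± 0.16 (log2, SD, n = 4), both beyond every named clone of the same sign. Of the 12 positive calls of at least 2-fold 11 were at unlisted spots, 10 of them in pairs 684 spots apart, and 69 of the 124 negative ones. Unlisted spots were not averaged, so each member of a pair counts as a call of its own. What these spots hold is not stated in the sources used here, and control or spiked-in sequences among them would not be liver transcripts.

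The first pattern is that 95.0% of the positive calls lay in the left blocks. A gradient of the ratio across the slide is a candidate explanation: 90.9% of the positive calls ended when the position surface was removed, when their median ratio went from 0.44 to 0.22 (log2) at a median SD of 0.16 before and after. Of the 58 that held, 79.3% lay in the left blocks, but they were selected from calls that mostly lay there. Of all 134 positive calls with the surface removed, 37.3% lay in the left blocks, against 50.7% of the tested clones. The ratio alone does not set the loss: with replicate 2 left out as well, 71.3% of the same clones ended at a lower median ratio of 0.15 and a median SD of 0.057. Of the 880 positive calls made without replicate 2, 77.4% ended when the surface was removed from the same arrays. In simulation the surfaces gave 0 calls on their own and 56.6 unchanged clones called per set when 200 clones were changed by 1 (log2), against 9.6 without them. The adjusted threshold loosens as more clones change, and 1344 clones were called in the data. These simulated counts therefore do not tell how many of the 638 positive calls a gradient could make. The layout is inferred and a surface can also remove real signal shared by neighbours, and no biological explanation was tested.

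The second pattern is that calls of at least 2-fold were mostly negative, 124 against 12. With the surface removed, 16.1% of the 124 ended and their median ratio went from -1.27 to -1.23 (log2). Calls of at least 2-fold were then 100 negative and 10 positive, so the imbalance stayed. Squares of 8 by 8 spots had medians between -0.89 and 0.64 on single arrays. A surface of that size could end few calls selected at 2-fold, so the small share that ended was largely given by this selection. That share therefore does not decide whether a gradient contributed. A bias of the ratio at dim spots may contribute: of the clones spotted more than once, 59 with a missing ratio on at least 1 spot had a median of -0.35 and 1613 with none a median of -0.01 (log2, position surface removed, difference -0.345, two-sided permutation p = 1e-05, the smallest that 100000 resamples can give). A bias limited to clones with a missing ratio is argued against, because those with none still gave 25 negative calls of at least 2-fold against 1 positive with the surface removed. The permutation p treats clones as independent, although they share the arrays and the pool, and does not measure the spread between rats. Without intensities a bias at dim spots in general stays open beside an effect of the treatment, which was not tested apart from it.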
